A study of Mus musculus with 11 samples.

How the data were processed

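DNA copy number was measured by array comparative genomic hybridization in 11 tumors that grew in the abdomen of mice hemizygous for TH-MYCN, a mouse model of neuroblastoma. The mice were 10 to 15 weeks old, per the labels. On each array, tumor DNA labelled with Cy5 was hybridised together with TH-MYCN spleen DNA labelled with Cy3, after digestion of 500 ng of DNA, per the labels' protocols. The labels do not say whether tumor and spleen came from the same mouse. No array with exchanged dyes was analysed here, so that any dye effect of a probe enters all 11 ratios with the same sign. The labels name the tumors as biological replicates 1 to 11, and they were treated as 1 group. Scanner records in the headers place the arrays on 4 slides, called A (tumors 1, 2, 3 and 10), B (tumors 4, 5 and 9), C (tumors 6, 7 and 11) and D (tumor 8), scanned on 3 dates.

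The arrays are of the Agilent design 015028 with positions on the mouse genome build mm7, per the file headers. The labelling protocol names another array model, and the headers were followed. The authors extracted the images with Agilent Feature Extraction 9.5.1.1, per the file headers. The deposited ratio of each feature is a log10 ratio of tumor over spleen signal, after background subtraction, spatial detrending and a linear dye normalisation within the array, per the file headers. The deposited signals of the separate channels are spot intensities on a linear scale. Quality marks of 0 or 1, set for each feature by the same software, were deposited beside them. A deposited table of the whole series holds log2 ratios for 42297 probes in the 11 tumors. Its values carry a further correction whose method is not given in the sources used here, so it served only as an alternative.

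Each array held 45220 features, of which 43020 were not controls. The log10 ratios were converted to log2, and features of the same probe were averaged. Probes marked as non-uniform or as saturated in either channel were left out of that array, which removed 0% to 0.358% of the features. Of 42404 distinct probes, 42012 had a position on a numbered chromosome or X, and 392 without one were left out of the comparisons. Each array was then centred on the median of its 40443 autosomal probes. The probes were 45 to 60 bases long. No genome of build mm7 was used here, so coordinates and gene names are those of the array files. Older symbols of listed genes were matched through a table of RefSeq gene names of assembly GRCm38.p6, from which no coordinate was taken.

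A chromosome was called gained or lost in a tumor where its median probe log2 ratio was at least 0.2 above or below 0, without a test. The mean of the chromosome medians over the 11 tumors was tested against 0 with an exact two-sided sign-flip permutation test over all sign assignments of the 11 arrays, whose smallest possible p is 0.000977, with Benjamini-Hochberg adjustment over 19 autosomes. Gene log2 ratios were the mean of the probes with that gene's name, for autosomal genes with at least 2 probes. They were tested against 0 with limma 3.58.1 in R 4.3.3 (intercept only, moderated by eBayes, two-sided, called at a Benjamini-Hochberg adjusted p under 0.05). They were tested once as they were and once after subtracting the median of the gene's chromosome in the same array. Focal segments were found in each array by penalised least squares with a penalty of 5 times the natural log of the number of probes, scaled by the noise variance, and at least 5 probes per segment. A focal gain or loss had a mean at least 0.2 above or below its chromosome median and covered under 90.0% of the chromosome's probes. Other calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots used matplotlib 3.10.9.

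Gene lists were fixed before the data were examined. They were the MYCN region, neuroblastoma driver genes, mouse orthologs of genes in the human regions of 1p36 loss, 11q loss and 17q gain, PRC2 subunits, sympathoadrenal transcription factors with catecholamine genes, the p53 pathway with DNA damage checkpoints, the spindle and mitotic checkpoint, and male-specific Y genes. The median of a list's genes with at least 2 probes was tested over the 11 tumors with the same sign-flip test, adjusted over 9 lists. The symbol Cyrib was left out of the MYCN region because the gene so named lies on chromosome 15. The antigen receptor loci Igh, Igk, Igl, Tcra/Tcrd, Tcrb and Tcrg, which lymphocytes of the spleen rearrange, were taken as the probes between fixed flanking genes, relative to the chromosome median. The flanks set for Tcra/Tcrd turned out to enclose 2 probes beyond Dad1, so a second interval between Olfr1508 and Dad1 was added after seeing the data.

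The genes named were set by a rule fixed before the data were examined. It takes every autosome past the threshold and the most often called gains and losses, up to 12 higher and 12 lower genes with the largest mean for each gene test (at most 3 per chromosome across tumors, and the same sign in at least 9 tumors within chromosomes), all members of the driver and MYCN region lists (apart from 2 whose values are not reported here), Th, the 10 focal segments with the largest absolute mean, and focal regions seen in 3 or more tumors. Other genes named are members of the lists or lie inside these regions, and the region on chromosome 2 of tumor 7 was singled out after its values were seen.

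The methods were tested on simulated data with independent normal noise, with the SD of the real genes and arrays. No outlying probes and no probe effects shared between arrays were simulated, so the rates below may not hold for the real arrays. In 10731 simulated genes the limma test called 2.0% of genes shifted by 0.05 log2, 22.0% at 0.1, 88.0% at 0.2 and 100.0% at 0.4, and 5 of 10531 unshifted genes. The segmentation recovered 54.5% of simulated segments of 10 probes shifted by 0.5 log2, 90.9% of segments of 20 probes shifted by 0.5, 27.3% of segments of 100 probes shifted by 0.2 and 100.0% of those shifted by 0.3. It recovered 0 of 11 simulated segments of 5 probes at 0.5 log2. Of 4000 simulated sets of 11 values with mean 0, 4.7% had a sign-flip p of 0.05 or less.

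Alternatives tried were other centrings (none, the mode, the median of chromosome medians), ratios of background-subtracted median signals, the series table, no filter on marked features, call thresholds of 0.1 and 0.3, limma or probe means for chromosomes, genes with at least 1 or 5 probes, a sign-flip test per gene, a reference within 5 Mb, penalties of 10 and 3, the mean over list genes, and leaving out each tumor. Added after seeing the data were a correction for the GC content of the probes, list values relative to the chromosome median, segments required to pass by mean and median, segments after subtracting each probe's median over the tumors, segments without tumor 10, and the second Tcra/Tcrd interval. The precision of a gene's mean is limited by the number of arrays and of its probes, and that of a segment by its number of probes. An effect of a probe that all arrays share is not measured by the spread between tumors or by a p-value drawn from it.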

Results

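Genomic copy number was profiled in 11 abdominal tumors of TH-MYCN hemizygous mice, in which a MYCN transgene under the control of the Th promoter is expressed in the sympathoadrenal lineage and gives rise to tumors that model neuroblastoma. Each tumor was hybridised once against TH-MYCN spleen DNA, so that a log2 ratio of 0 stands for the same relative copy number in both tissues. The 11 tumors formed 1 group of biological replicates. Values of single tumors have no replicate, and their error is given as the spread between probes or chromosomes of the same array. Each array held 42012 probes with a position, at a median spacing of 21.9 kb. The median tumor signal ranged from 473 intensity units in tumor 8 to 1082 in tumor 10, and the median spleen signal from 281 in tumor 8 to 829 in tumor 3. These signals lay 8.49 (tumor 6) to 23.6 times (tumor 3) above the negative controls in the tumor channel and 5.99 (tumor 8) to 19.3 times (tumor 3) in the spleen channel. The SD of the noise between neighbouring probes ranged from 0.13 log2 in tumor 9 to 0.29 in tumor 10. A gain of 1 copy in all cells of a diploid tumor would give a log2 ratio of 0.58, and a loss of 1 copy a ratio of -1. The profiles were compared to ask which chromosomes, regions and genes differed in copy number between tumor and spleen, in single tumors and across the 11 tumors.

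Whole-chromosome changes were present in 5 of the 11 tumors, with 2 gains and 7 losses. Chromosome 9 was lost in 3 tumors, at median log2 ratios of -0.30 in tumor 6, -0.23 in tumor 9 and -0.29 in tumor 11, over 2439 probes. Chromosome 3 was the only chromosome gained, at 0.36 in tumor 8 and 0.21 in tumor 7, over 2163 probes. Tumor 11 carried 4 losses, of chromosome 5 (-0.28), chromosome 6 (-0.31), chromosome 9 and chromosome 10 (-0.30), and tumor 9 also lost chromosome 16 (-0.36). Tumors 1, 2, 3, 4, 5 and 10 had no chromosome past the threshold of 0.2 log2. Taken relative to the median of each tumor's chromosomes and for diploid cells, the ratios are those of 1 extra copy of chromosome 3 in 58.5% of the cells of tumor 8 (0.37) and 33.0% of those of tumor 7 (0.22). For chromosome 9, on the same scale, they are those of 1 lost copy in 37.8%, 29.2% and 41.5% of the cells of tumors 6 (-0.30), 9 (-0.23) and 11 (-0.34).

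The called chromosomes stood well apart from the uncalled chromosomes of the same arrays, whose SD was 0.060 in tumor 9 and 0.038, 0.029, 0.027 and 0.023 in tumors 11, 6, 7 and 8. The 4 losses of tumor 11 shifted the centre of that array, and relative to the median of its chromosomes they measured -0.33 for chromosome 5, -0.36 for chromosome 6, -0.34 for chromosome 9 and -0.34 for chromosome 10. Intermediate medians that were not called were found for chromosome 3 in tumor 4 (0.16) and tumor 9 (0.15) and for chromosome 14 in tumor 9 (-0.13). Tumors hybridised on the same slide differed for chromosome 3, from -0.04 to 0.16 on slide B and from -0.02 to 0.21 on slide C. They also differed for chromosome 9, from -0.30 to -0.01 on slide C, whereas tumor 8 was the only tumor on its slide. These values are shown in the plot of chromosome medians by tumor.

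**Figure D1:**
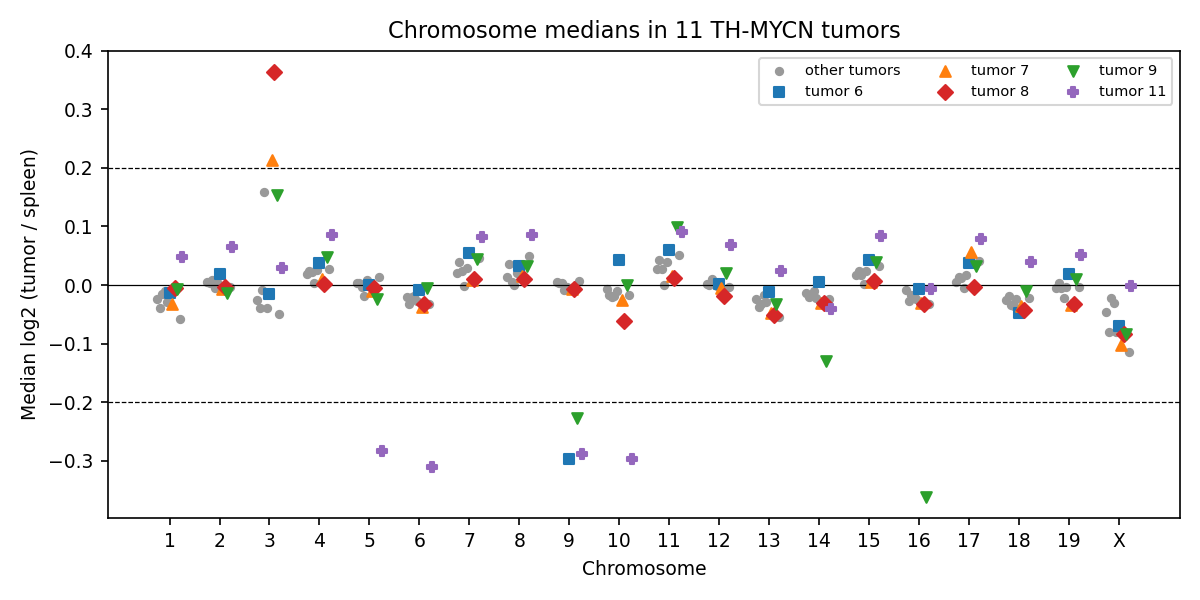
Median log2 ratio of tumor over spleen (y axis) of each autosome and X (x axis) in each of 11 tumors, 1 point per tumor, with tumors that carry a called chromosome in colour and dashed lines at the call threshold of 0.2 on either side of 0. Chromosome 3 reaches 0.36 in tumor 8, chromosome 9 lies between -0.30 and -0.23 in tumors 6, 9 and 11, and chromosome 16 lies at -0.36 in tumor 9.

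Averaged over the 11 tumors, neither of the recurrent chromosomes differed from 0 beyond the spread between tumors. The mean was 0.07 ± 0.14 (SD, n = 11) for chromosome 3 (exact sign-flip permutation test, p = 0.126, adjusted p = 0.16) and -0.07 ± 0.13 for chromosome 9 (p = 0.0908, adjusted p = 0.123). Without tumor 8 the mean of chromosome 3 was 0.04. By contrast, 11 other autosomes passed the test with shifts of 0.023 to 0.051 log2 in size, far below the ratio of a single-copy change in all cells. Chromosomes 4 (0.03), 11 (0.04 ± 0.03) and 15 (0.03) were above 0 in all 11 tumors, at an adjusted p of 0.00371 and a p of 0.000977, the smallest this test can give. Chromosomes 7, 8 and 17 each had a mean of 0.03 and passed as well. Chromosome 6 (-0.05 ± 0.09) and chromosome 16 (-0.05 ± 0.10) were below 0 in all 11 tumors, and chromosomes 13 (-0.03), 14 (-0.03) and 18 (-0.02) were below 0 in 10. The largest adjusted p among the 11 was 0.0236. The slide means of chromosome 11 were 0.04, 0.05, 0.06 and 0.01 on slides A to D. The size of the shift of chromosome 6 rested on tumor 11, without which the mean was -0.02, and that of chromosome 16 on tumor 9, without which it was also -0.02. These small shifts depended on the processing, since 9 autosomes passed after correction for probe GC content, 4 in the authors' series table and 2 of the 11 in all 3. With the mean of the probes in place of the median 0 autosomes were higher by the sign-flip permutation test (2 at an unadjusted p under 0.05), and with centring on the mode 1 was. Without further centring 0 were lower (1 at an unadjusted p under 0.05), and with limma 3 were lower, without chromosomes 6 and 16.

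The X chromosome had medians from -0.11 in tumor 10 to -0.0024 in tumor 11 over 1569 probes, so that no array showed the ratio of a 1-copy difference in X between tumor and spleen DNA. Relative to the uncalled autosomes, the X median lay between -0.11 and -0.02. The list of male-specific Y genes had 0 members on the array, and 1 probe, AK017055, was assigned to unplaced sequence of chromosome Y. Its signal was low in both channels in tumor 3 (139 units in tumor and 142 in spleen DNA) and tumor 9 (115 and 48.0). In tumor 11 it was 155 units in tumor and 1424 in spleen DNA, a log2 ratio of -3.21 that 0 of the array's 42012 placed probes reached. In the other 8 tumors the signal in tumor DNA was between 602 and 1254 units.

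Focal changes were called in 8 of the 11 tumors, as 10 gains and 33 losses, of which 14 were in tumor 9 and 11 in tumor 10. After subtracting each probe's median over the tumors, a run added after seeing the data, tumor 10 had 3 losses instead of 11 and tumor 5 had 13 instead of 4. In the same run tumor 9 had 10 gains instead of 3, tumor 7 had 8 losses instead of 3, and tumor 1 had 3 gains instead of 0. Few calls of that run were also past the threshold by their median, 3 in tumor 7, 3 in tumor 10 and 2 in tumor 11. In tumors 1, 3, 5 and 9 there were 0, so their added calls rested on outlying probes. Tumors 2 and 8 no longer had a call. The gain with the most probes in support among the largest segments was on distal chromosome 18 in tumor 7, from 85431030 to 88098436. Its 9 probes lay 0.55 ± 0.14 log2 above the chromosome median (SD between probes), in a segment of 2.67 Mb that holds Neto1 and Cbln2, which encode proteins of synapses. In the other 10 tumors the median of the same probes was between -0.04 and 0.19. Tumor 7 also carried a loss of 18 probes on chromosome 2, from 28560285 to 28974773, at -0.25 ± 0.13 relative to the chromosome median, with all 18 probes below it. This segment holds Tsc1, a tumor suppressor that restrains mTOR signalling, Gfi1b, a transcriptional repressor of blood cell development, Barhl1, a homeobox gene of neurons, and Ralgds, Cel, Gtf3c4, Gtf3c5 and Ddx31. The median of the other 10 tumors over these probes was -0.02 to 0.16.

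**Figure D2:**
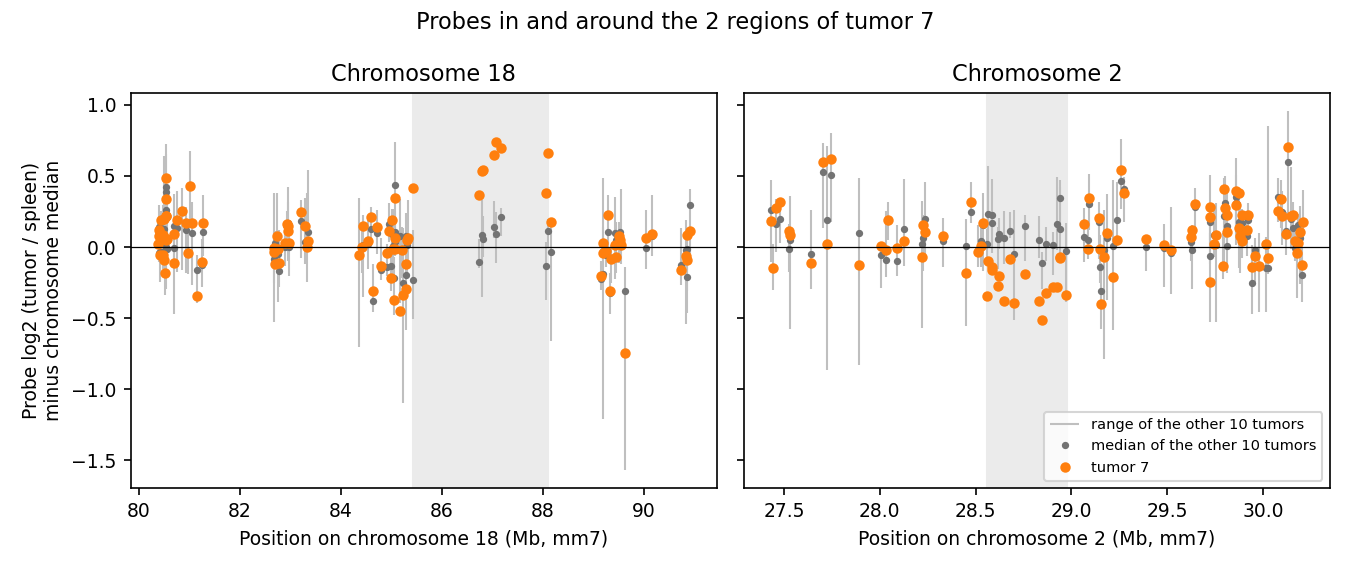
Probe log2 ratios of tumor over spleen minus the chromosome median (y axis) by position in Mb on build mm7 (x axis) around the chromosome 18 gain and the chromosome 2 loss of tumor 7, with tumor 7 in orange, the median of the other 10 tumors in grey, their range as vertical lines, and the called segments shaded. The 9 shaded probes on chromosome 18 average 0.55 in tumor 7, and the 18 on chromosome 2 average -0.25.

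Among the other segments with the largest means, a loss in tumor 10 on chromosome 1 from 59172191 to 59388029 covered 10 probes at -0.99 ± 0.74 and holds Als2cr2, Als2cr4, Mpp4 and Trak2. Tumor 10 also had a loss on chromosome 4 from 49590314 to 49664883 with a mean of -1.10 and a median of -0.76, which holds Rnf20, the E3 ligase that ubiquitinates histone H2B. This loss was not called after subtracting each probe's median over the tumors. Tumor 7 had a loss on chromosome 1 from 66952551 to 67070881 (-0.74, median -0.78) with Acadl, an enzyme of mitochondrial fatty acid oxidation, and Rpe. The probes at Rpe varied between arrays, since after the same subtraction the segment from 66951999 to 67052101 was at -0.55 (median -0.28) in tumor 7 and was called gained in tumors 9 (0.31) and 11 (0.60). Tumor 5 had losses on chromosome 5 from 87715717 to 87783111 (-0.73, median -0.30) with the casein genes Csnd and Csng, on chromosome 13 from 70277537 to 70472725 (-0.64, median -0.09) with Slc6a3, the dopamine transporter, and on chromosome 10 from 114853911 to 114929817 (-0.57, median -0.14) with Thap2. Tumor 9 had gains on chromosome 14 from 49077591 to 49127910 (0.78, median 0.09) with Dad1 and on chromosome 4 from 124105012 to 124147889 (0.61, median 0.14) with Utp11l, and a loss on chromosome 15 from 33148794 to 33708074 (-0.54, median -0.32) with Pgcp. After the same subtraction this loss was at -0.37 (median -0.15). Segments at Pgcp were then also called lost in tumors 3 (-0.44, median -0.08) and 5 (-0.25, median -0.02). Apart from the chromosome 1 loss of tumor 10, the segments of this paragraph had 5 probes each. Where the median of a segment called without that subtraction fell short of 0.2, a single probe carried at least 82.8% of the segment's deviation. Of the 43 segments, 29 were past the threshold in both mean and median.

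The same focal region was called in 3 or more tumors at 3 places, which hold clusters of related genes. On chromosome 7, the segment from 99388416 to 100422592 was lost in 3 tumors. It holds olfactory receptor genes such as Olfr631 and Olfr67 around the globin genes Hbb-y and Hbb-bh1, and the median of its 66 probes ranged from -0.29 to -0.14 over the 11 tumors. On chromosome 17, the segment from 18288794 to 21440857 was lost in 3 tumors. It holds vomeronasal receptor genes (V1re and V1rf), the formyl peptide receptor gene Fpr-rs3 and zinc finger genes, and its 68 probes had medians of -0.25 to -0.15. On chromosome 14, the segment from 21841258 to 23529961 was gained in 4 tumors. It holds Ppif, the mitochondrial cyclophilin, Anxa11 and Rps24, and its 33 probes had medians of 0.15 to 0.24. All 11 tumors thus lay on the same side of 0 in each of these regions, at a size near the threshold. After subtracting each probe's median over the tumors, which removes what most tumors share, none of these regions was called as a whole in any tumor, and only segments of 5 probes were called in the chromosome 7 region, a loss in tumor 7 (-0.33) and a gain in tumor 9 (0.22).

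Across the 11 tumors, many genes had small ratios that were the same in most tumors. Ube3b, a ubiquitin ligase on chromosome 5 (113620548 to 113640414), had the highest mean of 0.46 ± 0.19 log2 (SD, n = 11), followed by Bcl3, an IκB family regulator of NF-κB on chromosome 7 (17494821 to 17502599), at 0.44 ± 0.10. The lowest means were those of Ccr3, a chemokine receptor gene on chromosome 9 (123740993 to 123747564), at -0.58 ± 0.25, Plod2, a collagen lysyl hydroxylase (-0.56 ± 0.29), and Ankib1 (-0.55 ± 0.22). All of these had the same sign in all 11 tumors. In all, 2577 genes were higher and 2918 lower in tumor DNA of 10731 tested (limma, Benjamini-Hochberg adjusted p under 0.05).

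The other higher genes set by the naming rule were C4a of the complement system (0.41 ± 0.12), the retinoid receptor gene Rxra (0.39 ± 0.10), Padi1 (0.39 ± 0.14), Pvrl2 (0.39 ± 0.08), the cytokine receptor gene Il27ra (0.39 ± 0.07), Dci (0.38 ± 0.14), Laptm5, a lysosomal protein gene of blood cells (0.38 ± 0.05, adjusted p = 9.15e-08), the myogenic factor gene Myod1 (0.38 ± 0.10), 2610204M08Rik (0.37 ± 0.07) and the serine protease gene Htra3 (0.37 ± 0.19). The other lower genes were AW146242 (-0.53 ± 0.21), X62895 (-0.52 ± 0.09, adjusted p = 9.15e-08), Rnf20 (-0.52 ± 0.62, adjusted p = 0.0138, lower in 9 of 11 tumors), Olfr631 (-0.48 ± 0.34), AK139865 on chromosome 12 (-0.48 ± 0.18), AK164165 (-0.47 ± 0.39), the transcription factor gene Cebpd (-0.45 ± 0.14), Cnot6l of the deadenylase complex (-0.44 ± 0.27) and AK129341 (-0.44 ± 0.16). After correction for probe GC content the ratio fell to 0.28 for Ube3b, 0.22 for Bcl3 and 0.17 for Laptm5. It fell to 0.24 for C4a, 0.22 for 2610204M08Rik, 0.19 for Padi1 and 0.18 for Pvrl2. Plod2 (-0.37) and X62895 (-0.34) became smaller in size as well, while Rxra (0.32), Myod1 (0.32) and Ccr3 (-0.50) moved less. All genes named by the rule in this comparison became smaller in size and still passed. The median absolute shift of the called genes was 0.13 log2 among the higher and 0.15 among the lower, and 449 and 797 of them reached 0.2. In 997 of the higher and 1238 of the lower genes all 11 tumors had the same sign. Of the calls, 1289 higher and 1640 lower were also made with the same sign after GC correction and in the authors' series table. The shift was in part a property of single probes: among genes picked by their first probe in some of the tumors, the other probe showed, in the remaining tumors, 33.2% of the first probe's deviation.

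Relative to their own chromosome, which removes whole-chromosome gains and losses, 2955 genes were higher and 3208 lower of 10731 tested by limma. Ube3b (0.49 ± 0.16) and Bcl3 (0.41 ± 0.09) again had the highest means, and Pstpip1, a cytoskeletal adaptor gene on chromosome 9 (56131575 to 56145114), came next at 0.40 ± 0.11 (adjusted p = 4.77e-07). The remaining higher genes of the naming rule were Htra3 (0.40), C4a (0.38), Rxra (0.38), AK016429 (0.38), 2610204M08Rik (0.36), Padi1 (0.36), Dci (0.36), Il27ra (0.36) and Laptm5 (0.35). AK016429 lies on chromosome 14 at 22288513 to 22289077, inside the segment gained in 4 tumors. After GC correction the mean fell to 0.14 for Laptm5, 0.17 for Padi1, 0.20 for Bcl3 and AK016429 and 0.22 for C4a. Pstpip1 (0.34) and Rxra (0.31) moved less. The lowest means were those of Rnf20 (-0.55 ± 0.61, adjusted p = 0.0094), Ankib1 (-0.52), Olfr631 (-0.52), Ccr3 (-0.50), AK139865 (-0.49), Plod2 (-0.48), AW146242 (-0.48), X62895 (-0.47), AK044425 (-0.46), AK164165 (-0.42), Cnot6l (-0.42) and Prim2, the large primase subunit gene (-0.41 ± 0.39). When 1 tumor was left out, the mean of Rnf20 ranged from -0.62 to -0.39 within its chromosome and from -0.59 to -0.37 across tumors. Olfr631 lies inside the recurrent chromosome 7 segment. Of the lower genes 692 reached -0.2 or below, and of the higher genes 409 reached 0.2. The sign was the same in all 11 tumors for 1298 higher and 1366 lower genes. The share of calls that were higher was 47.9%.

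Of the neuroblastoma driver genes, 1 was higher, 6 were lower and 6 did not pass among 13 tested. The counts adjusted over the list alone were the same, 1 higher and 6 lower. Over all 10731 tested genes 51.2% passed, 2577 higher and 2918 lower. The counts of this list and of the other lists were not tested against that share. Hace1, a ubiquitin ligase gene on chromosome 10, was lower in all 11 tumors (-0.26 ± 0.09), as were the cell cycle inhibitor gene Cdkn2a on chromosome 4 (-0.23 ± 0.06) and Odz3 on chromosome 8 (-0.13 ± 0.08, but 0.01 after GC correction). Mdm2 (-0.11 ± 0.15) and Nf1 (-0.10 ± 0.08) were lower as well, as was Ptprd (-0.09 ± 0.13), which was at 0.02 in the authors' series table. Ptpn11 was higher (0.12 ± 0.16), a call that was lost in the series table (0.05, adjusted p = 0.321) and after GC correction (0.10, adjusted p = 0.0745). Alk (0.01 ± 0.08), Lmo1 (0.08 ± 0.15, past the threshold without tumor 6 at 0.11), Bard1 (-0.06 ± 0.10, and -0.03 without tumor 10), Tert (0.03 ± 0.05, but lower at -0.08 in the authors' series table, adjusted p = 0.0076) and Trp53 (0.06 ± 0.08, past the threshold at 0.07 without tumor 1 or 4) were among those that did not pass. After GC correction Alk (0.11, adjusted p = 0.00293) and Lmo1 (0.11, adjusted p = 0.0389) passed as higher and Tert (-0.10, adjusted p = 0.0014) as lower. Relative to its chromosome Tert was higher (0.06, adjusted p = 0.014) but took the opposite sign in the series table (-0.08) and after GC correction (-0.07). With a sign-flip permutation test per gene Bard1 passed as lower (adjusted p = 0.0491). The calls of Mdm2, Ptprd and Ptpn11 were each lost in 6 or 7 of the 11 runs that left out 1 tumor, with Ptprd at -0.06 without tumor 10, and that of Nf1 was lost after GC correction (-0.04) and in the series table (-0.05). Further drivers had 1 probe each and were tested among all genes with at least 1 probe, of which 10298 of 20027 passed. A value from 1 probe cannot be told apart from an effect of that probe. Of these drivers Lin28b (-0.37 ± 0.23) and Cdk4 (-0.22 ± 0.09) were lower, and Fgfr1 (0.09 ± 0.07) and Mycn (0.07 ± 0.06) were higher. Tiam1 (-0.17 ± 0.29), Hras1 (0.04 ± 0.10) and Nras (-0.0040 ± 0.09) did not pass. Th, the mouse gene whose rat counterpart gave the transgene its promoter, had 1 probe at -0.04 ± 0.12 and did not pass. On the X chromosome, Atrx had a mean of -0.21, from -1.10 in tumor 10 to 0.29 in tumor 4, and a mean of -0.12 without tumor 10. The median over the driver list was -0.04 ± 0.02 (below 0 in 11 of 11 tumors, sign-flip permutation test, adjusted p = 0.00439).

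The list of the MYCN region had a median of -0.18 ± 0.18 (adjusted p = 0.00586) over 2 tested genes. D12Ertd553e, the array's name for Fam49a, was lower in all 11 tumors (-0.16 ± 0.08). Ddx1, next to Mycn on chromosome 12 (13281955 to 13301009), had a mean of -0.20 ± 0.33 that did not pass (adjusted p = 0.0597). Ddx1 was at -1.07 in tumor 5, without which its mean was -0.11. After subtracting each probe's median over the tumors, the segment of tumor 5 that holds Ddx1 had 5 probes. Its mean was -0.41 with an SD of 0.88 between probes, but its median was -0.02, so most of its probes did not show a loss. Ddx1 passed as lower by limma without tumor 4 (-0.23, adjusted p = 0.042) and with a sign-flip permutation test per gene (adjusted p = 0.0357). By limma it also passed relative to its chromosome (-0.21, adjusted p = 0.0453), a call lost in 8 of 11 runs that left out 1 tumor. Adjusted over the list alone, 0 genes were higher and 2 lower, against 0 and 1 over all genes.

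In the list of the p53 pathway and DNA damage checkpoints, 7 of 11 tested genes were lower and 0 higher, and 7 lower and 2 higher when adjusted over the list alone. Atm, the kinase that signals double-strand breaks, was lowest (-0.33 ± 0.20, lower in 10 of 11 tumors), followed by Cdkn2a, Chek2 (-0.13 ± 0.13), Brca2 (-0.11 ± 0.09), Mdm2, Brca1 (-0.08 ± 0.07) and Mdm4 (-0.08 ± 0.09). The list median was -0.07 ± 0.06 (adjusted p = 0.00879). Cdkn2a, Mdm2 and Trp53 are also driver genes, and Atm and Chek1 are also in the 11q list. Of the sympathoadrenal transcription factors and catecholamine genes, 5 of 11 tested were higher and 0 lower, with the same counts adjusted over the list alone. The 5 were Isl1 (0.29 ± 0.13), the receptor tyrosine kinase gene Ret (0.16 ± 0.16), Chga of secretory granules (0.15 ± 0.05), the noradrenaline transporter gene Slc6a2 (0.12 ± 0.04) and Tcfap2b (0.11 ± 0.07). The list median was 0.09 ± 0.04, above 0 in 11 of 11 tumors (adjusted p = 0.00439).

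The mouse orthologs of the human 11q loss region all lie on chromosome 9, and the list median was -0.11 ± 0.14 (adjusted p = 0.0161). It was -0.35, -0.28 and -0.34 in tumors 6, 9 and 11, which lost that chromosome. Of 10 tested genes 4 were lower, namely Atm, Birc3 (-0.20 ± 0.15), Mre11a (-0.15 ± 0.18) and Fli1 (-0.14 ± 0.19), and 4 were lower when adjusted over the list alone. The list did not pass after GC correction (-0.10, adjusted p = 0.0678) or in the series table (-0.08, adjusted p = 0.149). The orthologs of 1p36, all on chromosome 4, had a median of 0.07 ± 0.06 (adjusted p = 0.0158), with Prdm16 higher (0.24 ± 0.06) and 4 of 5 tested genes not past the threshold. The orthologs of the human 17q gain region had a median of -0.04 ± 0.05 (adjusted p = 0.0176), with Ppm1d (0.16 ± 0.10) and Grb2 (0.14 ± 0.11) higher and Brip1 (-0.14 ± 0.09), Igf2bp1 (-0.13 ± 0.14) and Trim37 (-0.07 ± 0.05) lower of 7 tested. Its call was lost under 4 alternatives, among them the mean over genes (-0.02, adjusted p = 0.346). PRC2 subunits had a median of -0.01 ± 0.05 (adjusted p = 0.414), with Phf19 higher (0.28 ± 0.04) and the methyltransferase gene Ezh2 (-0.21 ± 0.12) and Jarid2 (-0.11 ± 0.04) lower of 7 tested. The spindle and mitotic checkpoint list had a median of -0.01 ± 0.03 (adjusted p = 0.177), but passed with the mean over genes (-0.03, adjusted p = 0.01) and with centring on the mode (-0.03, adjusted p = 0.0352). In it Cenpe (0.11 ± 0.15), Plk1 (0.11 ± 0.09) and Espl1 (0.09 ± 0.06) were higher and Bub1b (-0.18 ± 0.11), Bub1 (-0.16 ± 0.16), Ttk (-0.12 ± 0.15) and Rad21 (-0.07 ± 0.07) lower of 9 tested. In these lists the counts adjusted over the list alone equalled those over all genes. In all, 7 of 9 lists passed, and the plot of list genes shows 4 of them. Each test asked only whether the list median was shifted over the tumors. With 51.2% of all tested genes called across tumors, lists of other genes may pass as well, and none were tested. The adjusted p-values therefore do not set these lists apart from other genes.

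**Figure D3:**
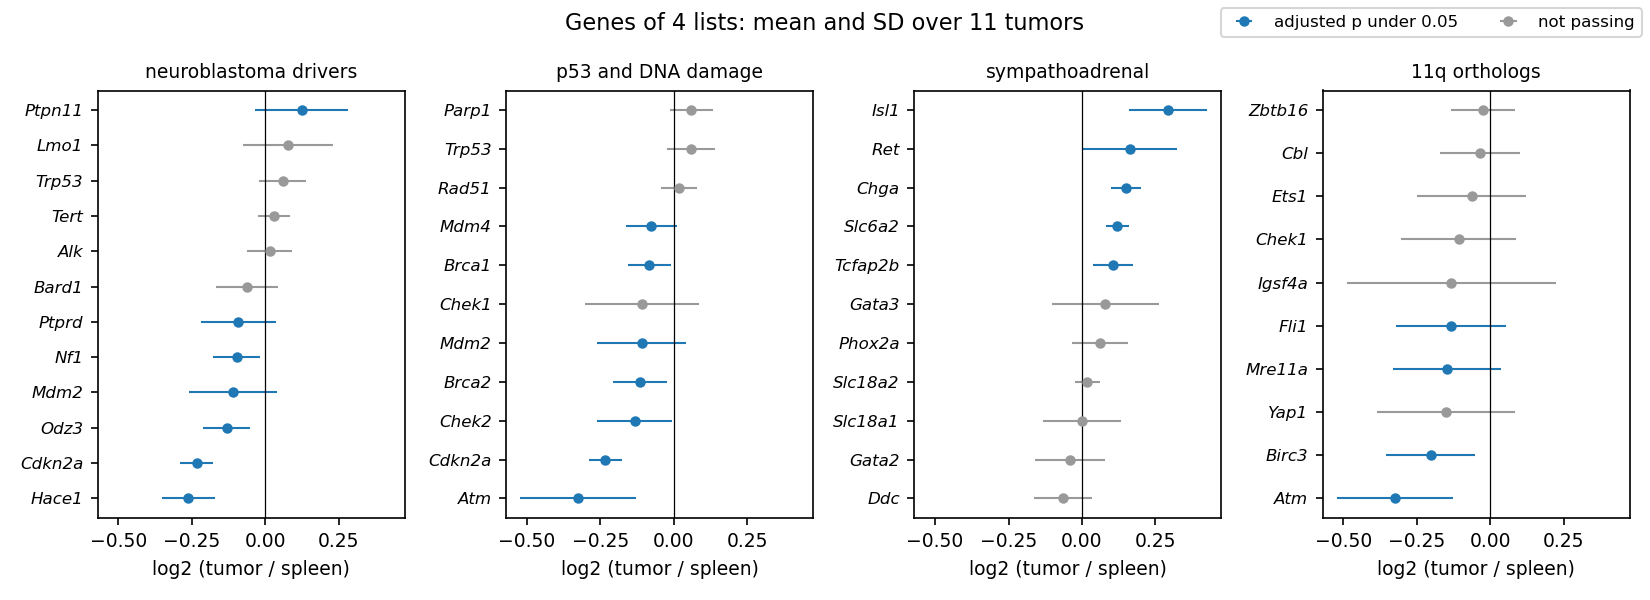
Mean log2 ratio of tumor over spleen (x axis) of the reported tested genes of 4 lists (y axis), with bars for the SD over 11 tumors and blue points for genes with a limma adjusted p under 0.05. Of the sympathoadrenal genes 5 passed above 0 with Isl1 at 0.29, and of the p53 and DNA damage genes 7 passed below 0 with Atm at -0.33. Over all tested genes 51.2% passed. Among the drivers, Odz3 moves to 0.01 after correction for probe GC content and Ptprd to 0.02 in the authors' series table.

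The antigen receptor loci, which serve as a DNA marker of spleen lymphocytes, had ratios below their chromosome median. Lymphocytes delete DNA between the segments they join, which by itself would place the ratio of tumor over spleen above 0. The Igk locus on chromosome 6 (67757797 to 70736728, 14 probes) was at -0.13 ± 0.07 and below 0 in 11 of 11 tumors (exact sign-flip permutation test, adjusted p = 0.00163). Tcrb on chromosome 6 (40821292 to 41515992, 17 probes) was at -0.12 ± 0.07 and below 0 in 10 of 11 (adjusted p = 0.00244). Tcrg on chromosome 13 (18556836 to 18717627, 4 probes) was at -0.08 ± 0.04 and below 0 in 11 of 11, but at -0.01 against the probes within 5 Mb. Igh on chromosome 12 (110778068 to 113765902, 9 probes) was at -0.05 ± 0.07 and below 0 in 9 of 11 (adjusted p = 0.0439). The Igh call was lost in 9 of 11 runs that left out 1 tumor, all but those without tumor 6 or 11, and it was also lost in the series table (0.03), with background-subtracted median signals and after GC correction. The interval set for Tcra/Tcrd on chromosome 14 (-0.12 ± 0.05) held 2 probes beyond Dad1 and so not the locus. The interval between Olfr1508 and Dad1 (48668460 to 49077650, 6 probes), added after seeing the data, was at -0.04 ± 0.05 (p = 0.0234). Igl had 0 probes. Relative to their chromosome 57.4% of 10731 tested genes passed by limma, 2955 higher and 3208 lower. The loci were not compared with other regions of similar size. Their p-values therefore do not set them apart from the rest of the genome.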

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

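The correction for probe GC content, the list values relative to the chromosome median, the segment rules that use the median or subtract each probe's median, the run of segments without tumor 10 and the second Tcra/Tcrd interval were chosen only after the results were seen; the other alternatives were planned. No paired analysis was possible because the 11 tumors form 1 group. The planned correction for local GC content was not run, because no genome of the array's build was used here. The 9 called chromosomes kept their call in all 63 recomputed values. With a call threshold of 0.1 there were 4 gains, and with 0.3 there were 1 gain and 2 losses, as the threshold sets by construction. Chromosomes shifted across tumors depended on the centring and the values used. The higher ones numbered 1 with centring on the mode, 2 in the series table and 0 with the mean of probes (sign-flip test, 2 at an unadjusted p under 0.05). The lower ones numbered 0 without further centring (sign-flip test, 1 at an unadjusted p under 0.05), 2 in the series table and 3 with limma, which was run only with the main centring; the cause was not tested. Leaving out 1 tumor lost none of the 11 shifted autosomes, and added chromosome 1 without tumor 11 and chromosome 10 without tumor 6. Counts of genes followed the number of genes tested: with at least 1 probe 5283 were higher and 5015 lower across tumors, and 5847 and 5468 within chromosomes, and with at least 5 probes 64 and 77, and 78 and 85. Of the calls across tumors, 74.6% were made again with the same sign after GC correction, 63.5% in the series table and 90.4% to 95.4% when 1 tumor was left out; within chromosomes these were 75.7%, 66.2% and 91.0% to 96.2%. None of the 24 largest genes of either comparison lost its call. Among recomputed values of named genes, 1374 stayed on their side of the threshold, 47 lost a call, 15 gained one and 8 changed sign. Across tumors Tert changed sign in the series table (-0.083) and after GC correction (-0.10), Ptprd (0.022) in the series table, and Odz3 (0.014) after GC correction. Within chromosomes Alk changed sign after GC correction (0.093), Tert in the series table (-0.079) and after GC correction (-0.074), and Ptprd in the series table (0.0067). The cause was not tested. Across tumors the call of Mdm2 was lost without tumor 2, 5, 6, 7, 8, 10 or 11, that of Ptprd without tumor 1, 2, 3, 5, 7, 9 or 10, and that of Ptpn11 without tumor 2, 5, 6, 7, 8 or 10, with means of -0.13 to -0.08, -0.11 to -0.06 and 0.10 to 0.16 over all such runs. Focal gains numbered 21 with background-subtracted median signals, 1 and 34 with penalties of 10 and 3, 3 and 52 with thresholds of 0.3 and 0.1, and 20 after subtracting each probe's median. Focal losses numbered 9 in the series table, 13 and 104 with penalties of 10 and 3, 9 and 173 with thresholds of 0.3 and 0.1, and 21 where mean and median had to pass. Penalty and threshold act by construction, and the other causes were not tested. Without tumor 10, 22 losses remained of 33. Of the 5 intervals tested for receptor loci, 3 passed in the series table, namely Igk, Tcrb and the interval set for Tcra/Tcrd, which does not hold its locus. Igh was at 0.027 there, at -0.041 with background-subtracted median signals, at -0.050 after GC correction and at -0.068 to -0.041 when 1 tumor was left out; its call was lost in the first 3 of these and in 9 of the 11 last. Tcrg was at -0.031 in the series table and -0.013 against probes within 5 Mb; the cause was not tested. Between 5 and 8 of 9 lists passed under every setting run. Low signal over background, 5.99 times in the spleen channel of tumor 8, and the noise of tumor 10 limit what single segments can show.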

Other observations

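In this part the receptor families, the sites of restriction enzymes, the share of calls kept after GC correction, the comparison within slides, the random placement of chromosome calls and, for the chromosome 18 region, the count of probes and the comparison with other tumors were chosen as tests only after the result was seen. The large chemosensory gene families lay slightly below their chromosomes in every tumor. Genes with at least 1 probe were taken here, unlike in the gene tests. The p-values were adjusted over both families under the main values, the GC correction and the series table. The 574 olfactory receptor genes, spread over 16 chromosomes, had a median of -0.05 ± 0.04 (SD, n = 11) relative to the chromosome median, below 0 in 11 of 11 tumors (exact sign-flip permutation test, p = 0.000977, the smallest possible, adjusted p = 0.00146). Of these genes 65.9% had a mean below 0, against 49.7% of other genes. The 53 vomeronasal receptor genes on 5 chromosomes were at -0.09 ± 0.05, also below 0 in 11 of 11 tumors (p = 0.000977), with 81.1% of genes below 0. After GC correction the medians were -0.07 and -0.08, but in the authors' series table they were 0.02 and -0.0038 (p = 0.0674 and 0.723), so that both families lost their shift there and the olfactory one changed sign.

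List members on the X chromosome were not tested. Stag2, a cohesin subunit gene, was at a mean of -0.26 over the 11 tumors and between -0.33 and -0.15 in each, and Rbbp7, a histone-binding PRC2 subunit gene, was at -0.14, between -0.28 and -0.05.

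The small shifts shared by most tumors concerned over 50% of tested genes, 51.2% across tumors and 57.4% within chromosomes. Random signs did not produce them. Of 100 sign assignments of the arrays, 1 gave as many genes, the real one, with 5495 genes against at most 1438 in any other. Within chromosomes it was also 1, with 6163 against 2249. Tumor DNA was in the same dye on all arrays, so a probe bias shared by the arrays would give this result too. The counts show that the arrays share the shifts and not what caused them. The part of the shifts that the probe GC correction removes was not the whole cause, since 75.7% of the calls within chromosomes were made again after it. That correction subtracts a median for probes of similar GC content. What it leaves, and the GC content around the probes, was not tested, so a further GC effect cannot be excluded. Effects of single probes, such as a dye or hybridization bias, remain a candidate explanation for most of the size, because a second probe of the same gene showed only 33.2% of the first probe's deviation (33.4% and 32.9% in the 2 ways of choosing tumors). The remainder is open, and a difference in DNA replication between tumor and spleen cells, in which late-replicating regions may lie lower, is a hypothesis that was not tested.

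Chromosome 9 was lost in 3 of 11 tumors and chromosome 3 was gained in 2 and intermediate in 2 more. A change in the spleen DNA was excluded, since the spleen channel moved against the ratio by at most 0.019 log2 while the tumor channel moved by 0.12 to 0.33 for chromosome 3 and by -0.27 to -0.20 for chromosome 9. A batch effect of slide or scan was excluded on slides B and C, where tumors of the same slide differed by at least 0.20 log2, but tumor 8 was the 1 array of its slide, so that for it batch and tumor cannot be told apart. Losses placed at random gave a chromosome lost in 3 tumors in 2.20% of random draws, whereas the 2 gains placed at random met on a chromosome in 5.29%. With 1 gain in each of 2 tumors no smaller share was possible, so this test decides nothing for chromosome 3, and it leaves out the medians of tumors 4 and 9. That loss of chromosome 9 is recurrent in these tumors is a hypothesis, and no biological explanation was tested.

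The distal chromosome 18 gain of tumor 7 lies toward the end of the chromosome, whose last probe ends at 90910037. It was not made by outlying probes, since 9 of 9 lay over 0.2 log2, nor by the spleen DNA, whose channel moved against the ratio by -0.0095 log2 (SD 0.050 over the other tumors) while the tumor channel rose by 0.51. None of the other 10 tumors had a gain of that size, with a region median at most at the 96.6th percentile of windows of 9 probes in their own array. That highest value was in tumor 8, whose median was 0.19 with 4 of 9 probes over 0.2, and because 0 of 11 simulated segments of 10 probes at 0.2 log2 were recovered, a smaller gain there could not be excluded. Because the TH-MYCN transgene is known to have integrated on distal chromosome 18, a candidate explanation is a gain of the transgene with its flanking DNA in this tumor. The array positions were not compared with the integration site, so this hypothesis is untested.

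Probes that hold a restriction site stood apart on some arrays, with no explanation tested. The 49 probes with an AluI site were dim on slide C, at -2.10 to -1.97 log2 against the array median in tumor DNA and -2.29 to -2.09 in spleen DNA, and at -0.54 to -0.35 and -1.06 to -0.36 on slide B. On slide D, which held tumor 8, they were at -1.13 and -0.79, with a median ratio of -0.24. In tumor 10 they were at -1.30 in tumor and -0.25 in spleen DNA, with a median ratio of -0.98, and the 30 probes with an RsaI site had a median ratio of -0.63. The ratio of the AluI probes ran both ways, with medians of 0.41 in tumor 4 and 0.28 in tumor 3 but -0.31 in tumor 2. The 6058 probes with a DpnII site were within 0.06 of the array median in both channels of all arrays. Over probes, the ratios of 2 arrays correlated across probes, which are not independent, with a median r of 0.59 over 55 pairs, from -0.30 (tumors 4 and 10) to 0.81 (tumors 2 and 8), and 0 probes had exactly equal log2 values, with no tolerance, in the closest pair. The r between probe GC content and ratio was 0.23 to 0.46 over the arrays.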
